A study of Mus musculus with 2 samples.

How the data were processed

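Single-cell RNA sequencing by the 10x Genomics 3' method was run on LSK cells, the lineage-negative fraction of mouse bone marrow that carries both Sca1 and c-Kit and that holds the blood stem cells and multipotent progenitors. There were 2 libraries from C57BL/6J mice, 1 from control animals and 1 from animals taken 15 days after 5 Gy of total body irradiation. How many animals went into each library was not stated. Both libraries were sorted by flow cytometry on the same surface markers. Groups were taken from the treatment stated for each library.

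The values deposited by the authors are raw counts of unique molecular identifiers (UMIs), 1 whole number per gene and barcode, for barcodes called as cells in each library. The authors' processing notes name Cell Ranger 2.1.1 and the mouse build mm10, while the matrix headers give software version 3.1.0. The disagreement was left as it stands. Gene symbols and identifiers came from the files (31053 genes), and coordinates came from GENCODE M21 on the same build (GRCm38), in which 31011 of the 31053 identifiers were found. A symbol shared by more than 1 identifier was kept apart by its identifier.

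Barcodes were kept with at least 1000 UMIs, at least 500 detected genes and at most 10% of UMIs from mitochondrial genes. This removed 496 of 7686 control barcodes and 468 of 5596 irradiated barcodes. Scrublet scored doublets in each library alone with an expected rate of 0.06 and marked 1 control cell and 16 irradiated cells, 0.0139% and 0.312% of the cells, far below the expected rate. Doublet removal by this route has therefore not worked here, and an alternative without the 6% of cells with the highest scores in each library was added after the data were seen. After both steps 7189 control cells and 5112 irradiated cells remained, with 138113621 and 162741683 UMIs in all.

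UMIs were summed over the kept cells of each library and divided by the library total to give counts per 1000000 UMIs (CPM). Each gene's log2 ratio of irradiated over control CPM carries an exact 95% interval, which is the Clopper-Pearson interval conditional on the gene's total in both libraries. With a mean CPM of at least 20 over the libraries a gene was listed, and it was called different by size when its CPM ratio was at least 2 either way. There was 1 library per group, so no test was possible and no p-value is given. All intervals cover counting error only and say nothing about variation between animals.

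The lists comprised 40 gene groups, all fixed before the data were examined, of which 12 were cell type marker lists. The others cover p53 targets, DNA repair, S phase, G2/M phase, HSC (haematopoietic stem cell) quiescence, Hox factors and partners, interferon response, MHC class I and class II, NF-kB and inflammation, immediate early genes, heat shock, the unfolded protein response, antioxidant genes, glycolysis, nuclear oxidative phosphorylation, mitochondrially encoded subunits, ribosomal proteins, cholesterol synthesis, pro- and anti-apoptotic genes, senescence, TGF-beta and Id genes, adhesion and homing, chromatin regulators, sort and stem surface genes, sex-linked genes and haemoglobins. For each list with at least 3 members at a mean CPM of at least 5, the median log2 ratio was placed among 10000 random lists of equal size, matched on mean expression in 20 bins. The percentile describes these libraries and is not a test. A member was counted as higher or lower when its CPM ratio was at least 1.25 either way.

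Cells were clustered on log-normalised values of 2000 variable genes (cell cycle lists, ribosomal, mitochondrial and sex-linked genes left out) reduced to 30 principal components. Each cell took 15 neighbours from each library, so that library size did not set the graph, and Leiden clustering ran at resolution 1 on the shared-neighbour graph. The naming rule was set after the data were seen. A cluster took the name of a marker list when at least 3 of its markers stood among the 25 genes with the highest fold over all other cells, at least 3 were detected in at least 10% of its cells, and no other list had more markers among the top 10. Clusters that met no list stayed unnamed. Expression was compared within a class only where each library held at least 100 of its cells, which left HSC, lymphoid-primed, megakaryocyte-primed and neutrophil-primed classes.

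Cell cycle phase was called with the cell cycle scoring of scanpy, after each cell had been thinned to 5000 UMIs. Kept cells below that depth, 66 control and 59 irradiated, were left out of the phase calls. Cells with at least 1 UMI of Mki67 were counted among the same thinned cells. Shares of cells carry exact 95% Clopper-Pearson intervals.

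The rule for named genes was fixed before the data were examined. Over all cells it takes the 12 genes with the highest and the 12 with the lowest ratio at a mean CPM of at least 20, leaving out predicted, mitochondrial and ribosomal protein genes. In every list it takes up to 2 members each way plus the most abundant member. A fixed set of stem cell, cycle and damage genes (Cdkn1a, Mki67, Ly6a, Kit, Flt3, Procr, Slamf1, Cd34, Cd48, Mpo and Xist) was always included. In each compared class it takes the 5 highest and the 5 lowest genes at a mean CPM of at least 50. For the named genes, the share of UMIs held by the 10 cells with the most was also computed.

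There were 44 alternatives planned before the data were examined, and 9 were added afterwards. They vary the cell filters, the doublet removal, the scaling (median of ratios, mean of each cell's CPM, thinning to 5000 UMIs), the CPM minimum and ratio threshold, the clustering (resolution 0.5 and 2, 30 neighbours from all cells, thinned cells, cycle genes allowed, each cell named by its own highest marker mean) and the phase call (thinning to 2500 or 10000 UMIs, none, or at least 5 UMIs over the G2/M list). Those added afterwards leave marker genes out of clustering, leave out the 6% of cells with the highest doublet scores, or leave out each gene's 10 cells with the most UMIs in each library.

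The calculation was tested on simulated data in which 200 of 5247 genes were given a known ratio. All 50 genes set 3-fold higher and all 50 set 3-fold lower passed the 2-fold threshold, and 0 of 100 genes set at 1.5-fold and 0 of 5047 unchanged genes did so. The exact intervals covered the true ratio for 93.0% of genes, below the 95% they are set for. The simulated counts held counting error only, so UMIs gathered in a few cells were not simulated. Of 200 random lists, 6% fell outside the central 95% of the random medians. The software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9. Random steps used seed 1.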

Results

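The data describe mouse bone marrow LSK cells, a lineage-negative, Sca1-positive and c-Kit-positive sort fraction that is rich in blood stem and multipotent progenitor cells. There was 1 control library and 1 library from mice 15 days after 5 Gy of total body irradiation, so no replicate error can be given and every value below describes these libraries alone. The control library held 7686 barcodes and 139274656 UMIs, and the irradiated library held 5596 barcodes and 165119247 UMIs. After filtering, 7189 control cells had a median of 16084 UMIs and 3702 genes, and 5112 irradiated cells had a median of 29615 UMIs and 4833 genes. The median mitochondrial share was 4.38% in control and 3.24% in irradiated cells. Ddx3y and Eif2s3y, both Y-linked, were present in each library (50.9 and 37.9 CPM for Ddx3y, 65.9 and 51.6 CPM for Eif2s3y), and Xist, the X-inactivation transcript, stood at 0.181 and 0.104 CPM.

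The first comparison asks which progenitor classes filled the sorted gate in each library. Cells with the stem cell programme and with lymphoid priming made up a smaller share of the irradiated library, while neutrophil-, megakaryocyte- and erythroid-primed cells made up a larger one. HSC-like cells, marked by Hlf and Mecom, with Procr among the top genes of only the smaller of their 2 clusters, were 25.8% (95% interval 24.8 to 26.8) of control cells and 7.71% (6.99 to 8.47) of irradiated cells. Lymphoid-primed cells, marked by Flt3, Dntt and Satb1, were 24.9% (23.9 to 25.9) and 3.78% (3.27 to 4.33). Neutrophil-primed cells, marked by the granule protease genes Ctsg and Prtn3 and by Mpo, with Elane leading only the larger of their 2 clusters, were 5.42% (4.91 to 5.97) and 33.1% (31.8 to 34.4).

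Megakaryocyte-primed cells, marked by Pf4, Itga2b and Gp5, were 2.94% (2.56 to 3.35) of control and 10.3% (9.53 to 11.2) of irradiated cells. Erythroid-primed cells, marked by Klf1, Car1 and Aqp1, were 0.473% (0.328 to 0.660) and 8.88% (8.12 to 9.69), which is 34 and 454 cells. A cluster led by Cd74 and class II MHC genes, with Irf8, Xcr1 and Clec9a of differentiated dendritic cells, held 0.389% and 1.56%; it met the monocyte/dendritic-primed markers, but these genes go against the name of a progenitor. B lineage cells with Ebf1, Vpreb1 and Cd79a were 1.52% and 0.469%, and T/NK lineage cells with Trbc1 and Tcf7 were 0.640% and 0.978%. A further 37.9% of control and 33.1% of irradiated cells lay in a pair of clusters led by proliferation genes, Top2a and Mki67 in one and Mcm3 in the other, and took no class name. No cluster met the markers of mast cells or basophils, mature neutrophils, macrophages, or endothelial and stromal cells, which does not show that such cells were absent: at a limit of 5% mitochondrial UMIs a mast cell and basophil cluster held 0.805% of control and 0.863% of irradiated cells. At that limit no cluster took the T/NK lineage name. Whether the clusters share cells was not tested.

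Some classes were close to specific to 1 library. The larger neutrophil-primed cluster drew 90.7% of its cells and the erythroid-primed cluster 93.0% from the irradiated library, and the lymphoid-primed cluster drew 9.75% from it. The neutrophil-primed class of the control library came mostly from the other of its clusters (278 of 390 cells), and that of the irradiated library mostly from the larger one (1092 of 1694 cells). With the marker genes left out of clustering, HSC-like cells were 21.8% and 5.26%, lymphoid-primed cells 34.6% and 8.29%, neutrophil-primed cells 1.61% and 21.9%, megakaryocyte-primed cells 2.55% and 9.62%, and erythroid-primed cells 0.626% and 9.19%. Every alternative kept the direction for these 5 classes where it gave them a cluster, but the size of the difference moved: the lymphoid-primed difference was -21.1 points and reached -42.3 points with 30 neighbours from all cells, the HSC-like difference was -18.1 and became -11.6 points at a limit of 5% mitochondrial UMIs, the erythroid-primed difference was 8.41 and became 16.1 points at resolution 0.5, where the megakaryocyte-primed cells joined that cluster, and the megakaryocyte-primed difference was 7.41 and became 3.49 points when each cell was named by its own markers. The difference for T/NK lineage cells, 0.338 points, changed sign under that last naming (-0.102 points).

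**Figure D1:**
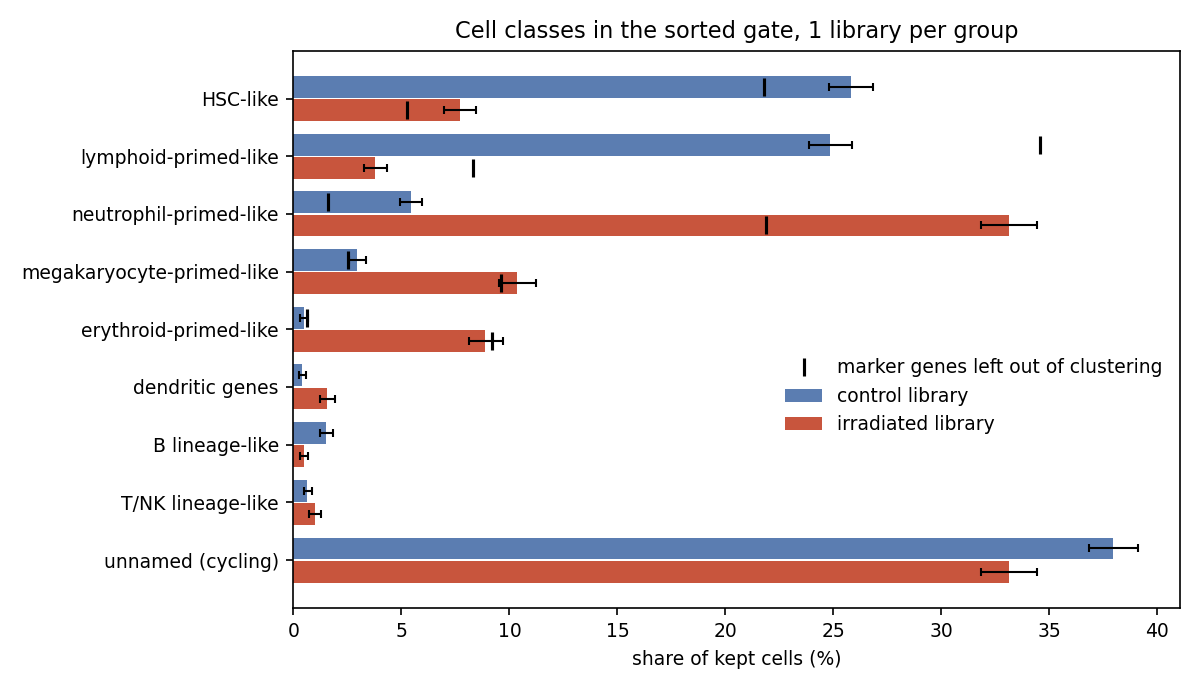
Share of kept cells in each class (horizontal axis, %) in the control and irradiated libraries, 1 library each; bars with exact 95% intervals for counting error, and black ticks for the 5 largest named classes with marker genes left out of clustering. Neutrophil-primed cells stand at 5.42% and 33.1%, and HSC-like cells at 25.8% and 7.71%.

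The next comparison asks which genes differed in level over all cells of each library. Of 5247 genes with a mean of at least 20 CPM, 58 were at least 2-fold higher and 125 at least 2-fold lower in the irradiated library, and 58.4% lay inside the narrower ratio used for list members. In each pair of CPM values the control library comes first. The highest ratio was that of the immunoglobulin gene Igha, which rested on a few cells as given below. The next highest belonged to genes of neutrophil, monocyte and erythroid differentiation and to metallothionein. The gene Elane for neutrophil elastase (ENSMUSG00000020125, chromosome 10, 79886247 to 79888215, GRCm38) stood at 93.3 CPM in control and 741 CPM in irradiated cells, a log2 ratio of 2.99 (2.96 to 3.01). Ms4a3 (ENSMUSG00000024681, chromosome 19, 11629496 to 11640851), a marker of granulocyte and monocyte progenitors, stood at 25.8 and 386 CPM, a log2 ratio of 3.90 (3.85 to 3.95). Mt1 (ENSMUSG00000031765, chromosome 8, 94179082 to 94180327), which encodes a zinc-binding metallothionein, stood at 19.1 and 300.5 CPM, a log2 ratio of 3.98 (3.92 to 4.03).

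Other genes with the highest ratios were Car1, a carbonic anhydrase of early erythroid cells (13.1 and 169 CPM, with 76.0% of its control UMIs in 10 cells, and 3.14 and 153 CPM without the 10 highest cells of each library), the granule genes Ctsg (300.1 and 1486 CPM) and Mpo (387 and 1422 CPM), Trem3, Hp, Anxa3, and the monocyte genes Ly6c2 and Ccr2. The Igha count was 8260 UMIs in the irradiated and 4 in the control library, and 2 irradiated cells held 8027 of them. On the lower side, Hlf, a transcription factor of stem cells (ENSMUSG00000003949), stood at 142 and 31.8 CPM, a log2 ratio of -2.16 (-2.21 to -2.12). The chemokine genes Ccl3 and Ccl4 were 6.41-fold and 4.61-fold lower in the irradiated library. The lowest ratios also included Shisa8, Ldhb, Klk8, Nkx2-3, Ltb and Wfdc17, with log2 ratios between -2.67 and -2.21. S100a9 and S100a8, made in maturing neutrophils, had log2 ratios of -3.58 and -2.45, but 10 control cells held 87.3% and 87.9% of their control UMIs. For Iglc1, a light-chain gene, 1 control cell held 15278 of 15554 UMIs, and its ratio turned to the higher side when each cell counted equally (log2 0.59) and when cells were thinned to 5000 UMIs (0.62).

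The lists of cell type markers differed in the directions of the class shares. All 6 measured HSC markers and all 7 measured lymphoid-primed markers were lower in the irradiated library, with median log2 ratios of -1.26 and -1.45 (both at percentile 0 of the random lists). Slamf1, an HSC marker below the CPM minimum and so not measured here, was higher. Of the neutrophil-primed markers 8 of 9 were higher (median 1.88, percentile 100), as were 9 of 10 erythroid-primed markers (2.05, percentile 100, between 1.19 and 2.69 over the alternatives), with Car2 lower, and 7 of 10 monocyte/dendritic-primed markers (0.65, percentile 100), with Klf4 lower. Of 6 megakaryocyte-primed markers 3 were higher, Cd9 and Pf4 among them, and Plek was lower (median 0.35, percentile 99.2); at a mean CPM of at least 20 the median was 0.40 and the percentile 96.1. The 4 measured mast cell and basophil markers had a median of 0.44 (percentile 99.3; 0.30 at percentile 96.1 with each cell weighted equally), the 6 B lineage markers -1.98 (percentile 0, between -2.65 and -1.20 over the alternatives) and the 5 mature neutrophil markers -3.41 (percentile 0), which rested largely on a few cells, since it was -0.93 (percentile 1.945) without each gene's 10 cells with the most UMIs. Only 1 T/NK marker, 2 endothelial or stromal markers and 0 macrophage markers reached the minimum, so these lists have no median. The 4 haemoglobin genes measured had a median of 1.52 (percentile 99.99, between 1.04 and 2.43 over the alternatives), with 94.2% of the control and 88.8% of the irradiated UMIs of Hba-a1 in 10 cells of each library.

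Stem cell quiescence genes and stimulus-responsive genes were lower over all cells. Of 10 quiescence genes 8 were lower (median -1.08, percentile 0), among them Txnip (119 and 39.2 CPM) and Egr1 (269 and 85.1 CPM). Of 17 immediate early genes, which are transcribed within minutes of a stimulus, 15 were lower (median -1.17, percentile 0), with Fos at 1050.2 and 514 CPM and Fosb at 363 and 129 CPM. Of 15 NF-kB and inflammation genes 13 were lower (median -0.73, percentile 0), and of 8 Hox factors and partners 7 were lower (median -0.66, percentile 0.240), Meis1 among them (137 and 53.9 CPM). TGF-beta and Id genes had a median of -0.60 (percentile 0.0500), with Smad7, an inhibitor of that pathway, 2.44-fold lower. Within HSC-like, lymphoid-primed, megakaryocyte-primed and neutrophil-primed cells the NF-kB medians were smaller in size, at -0.39, -0.10, -0.006 and -0.34. In that order the Hox medians were -0.04, -0.38, -0.20 and -0.35. Those of TGF-beta and Id genes were 0.02, -0.06, -0.20 and -0.36. The differences of these lists over all cells may therefore rest in part on the mix of classes, which was not tested for them.

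Interferon response genes were higher over all cells: 15 of 24 members were higher and 3 were lower, with a median of 0.56 (percentile 100). Isg15, a ubiquitin-like protein gene, stood at 13.1 and 29.5 CPM, and Irf7, a transcription factor of the pathway, at 20.8 and 44.9 CPM. MHC class I genes had a median of 0.06 (percentile 41.3). G2/M genes were higher in 25 of 52 cases (median 0.30, percentile 100), and S phase genes in 9 of 38 (median 0.13, percentile 83.0), with Rrm2, a subunit of ribonucleotide reductase, 2.33-fold higher. Mki67, a marker of proliferating cells, stood at 157 and 166 CPM, a log2 ratio of 0.08 that was 0.47 with each cell weighted equally.

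Among lists tied to radiation damage, p53 targets, DNA repair, anti-apoptotic and senescence genes lay inside the central 95% of random lists over all cells, and pro-apoptotic genes lay above it. Of 14 p53 targets 3 were higher and 7 lower (median -0.28, percentile 12), with the apoptosis gene Bax at 92.1 and 133 CPM and Btg2 at 241 and 93.3 CPM. Cdkn1a, which encodes the cell cycle inhibitor p21, stood at 104 and 77.5 CPM. DNA repair genes had a median of -0.16 (percentile 11.6), and 17 of 24 were neither higher nor lower. Pro-apoptotic genes had a median of 0.38 (percentile 99.9), with Cycs and Bak1 higher and Bcl2l11 2.05-fold lower. Anti-apoptotic genes had a median of -0.31 (percentile 10.5) and senescence genes 0.07 (percentile 42.9).

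The comparison was then made within the 4 classes that held at least 100 cells in each library, to hold the mix of classes fixed as far as the clusters allow. Interferon response genes were higher in the irradiated cells of each class, and stem cell quiescence and mitochondrially encoded genes were lower. The interferon median was 0.85 in HSC-like cells (21 of 26 members higher), 1.11 in lymphoid-primed cells (23 of 26), 0.86 in megakaryocyte-primed cells (20 of 24) and 0.54 in neutrophil-primed cells (15 of 23), each at percentile 100. Ifi27l2a, an interferon-induced gene, stood at 42.8 and 242 CPM in HSC-like cells, a 5.65-fold higher level (log2 interval 2.38 to 2.62), at 164 and 588 CPM in lymphoid-primed cells and at 25.1 and 111 CPM in megakaryocyte-primed cells, but was lower in neutrophil-primed cells (152 and 128 CPM). Irf7 stood at 26.3 and 87.4 CPM in HSC-like cells, a log2 ratio of 1.73 (1.56 to 1.90).

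The quiescence list had medians of -0.51, -0.54, -0.57 and -0.75 in HSC-like, lymphoid-primed, megakaryocyte-primed and neutrophil-primed cells, at percentiles up to 0.0300. With 30 neighbours from all cells the HSC-like median was -0.086 (percentile 15.2) and the neutrophil-primed one -0.16 (percentile 6.07), and at a limit of 5% mitochondrial UMIs the latter was -0.21 (percentile 6.40), so neither stood apart from random lists there. Immediate early genes had medians of -0.48, -0.28, -0.36 and -0.57 in the same order (each at percentile 0), and the neutrophil-primed value did not hold its side under other cell sets, with 0.02 for all barcodes and 0.05 with 30 neighbours from all cells, and 0.01 (percentile 42.7) in the larger of its 2 clusters alone. The 13 mitochondrially encoded genes had medians of -0.27, -0.24, -0.26 and -0.26 in that order, with -0.06 (percentile 3.92) in the larger neutrophil-primed cluster alone, beside a median mitochondrial share of cells that was lower in the irradiated library as a whole. The p53 target medians lay between -0.08 and 0.04 in the 4 classes. Under the alternatives they ran from -0.09 to 0.31, -0.30 to 0.20, -0.07 to 0.14 and -0.37 to 0.09 in that order. Their percentiles reached 99.85 in HSC-like and 99.59 in lymphoid-primed cells, and fell to 0.85 in neutrophil-primed cells. In megakaryocyte-primed cells the percentiles stayed between 45.53 and 89.08. Of 10 alternatives 9, 9, 10 and 8 left the list as reported in that order. Cdkn1a, lower over all cells, was higher in the irradiated cells of each class, with log2 ratios of 0.34 (0.21 to 0.46), 0.50 (0.38 to 0.62), 0.65 (0.45 to 0.86) and 0.22 (0.08 to 0.36) in that order, and kept that direction under all 10 alternatives run within classes.

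The genes with the highest ratios in HSC-like cells were Ifi27l2a, Gem, Lgals1, Ctsg and Irf7, with 10 irradiated cells holding 34.3% of the Ctsg UMIs, and the lowest included Ccl3, Klk8, Ldhb and Ndrg1. Lymphoid-primed cells had Lgals1, Ctsg (40.9% of UMIs in 10 irradiated cells), Gem and Ifi27l2a among the highest, and Hbb-bt, for which 10 irradiated cells held 77.1% of the UMIs. Their lowest were Klk8, Ccl3, Ptms, Txnip and Hlf. Megakaryocyte-primed cells had Ifi27l2a, Mt1, Cd48, Ly6a and Lgals1 as the highest and Prss34, Mcpt8, Ccl3 and Ccl4 among the lowest, and 10 control cells held 99.7% of the control UMIs of Prss34 and 99.2% of those of Mcpt8, both mast cell and basophil protease genes, with 84.3% for Ccl3 and 78.8% for Ccl4. The Mcpt8 ratio turned to the higher side with all barcodes (log2 1.00) and at a limit of 5% mitochondrial UMIs (0.86). Neutrophil-primed cells had Mt1 (92.9 and 450 CPM), Ms4a3 (254 and 796 CPM), Ly6a, Gstm1 and Trem3 as the highest, and these sizes depend on the mix of their 2 clusters: Mt1, Ms4a3 and Trem3 are among the top genes of the cluster that holds most irradiated cells of the class, and over the alternatives Ms4a3 ran from 1.81-fold to 4.22-fold higher and Trem3 from 1.44-fold to 2.85-fold. Their lowest were Ngp, S100a9, Camp and S100a8, for which 10 control cells held between 95.4% and 99.5% of the control UMIs, and Ptms.

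The genes of the sort markers also differed within classes. Ly6a, which encodes Sca1 (ENSMUSG00000075602), was 2.05-fold higher (95% interval 1.96 to 2.14) in irradiated HSC-like cells, 2.23-fold (2.11 to 2.35) in lymphoid-primed, 2.52-fold (2.19 to 2.91) in megakaryocyte-primed and 2.65-fold (2.45 to 2.87) in neutrophil-primed cells. In erythroid-primed cells, with only 34 control cells, it was 4.10-fold higher (2.43 to 7.53). Kit, which encodes c-Kit, was lower in the irradiated cells, at 217 and 155 CPM in HSC-like, 138 and 91.0 CPM in lymphoid-primed, 186 and 100.1 CPM in megakaryocyte-primed and 74.5 and 58.0 CPM in neutrophil-primed cells. Over all cells Ly6a stood at 156 and 218 CPM, Kit at 132 and 73.5 CPM, Cd34 at 369 and 231 CPM, Flt3 at 127 and 46.4 CPM, Cd48 at 166 and 217 CPM, Procr at 14.7 and 5.42 CPM and Slamf1 at 2.19 and 6.37 CPM. The list of 11 sort and stem surface genes had a median of -0.54 (percentile 0.06), its sign turned with no CPM minimum (0.30), and it was -0.03 (percentile 23.3) with each cell weighted equally.

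**Figure D2:**
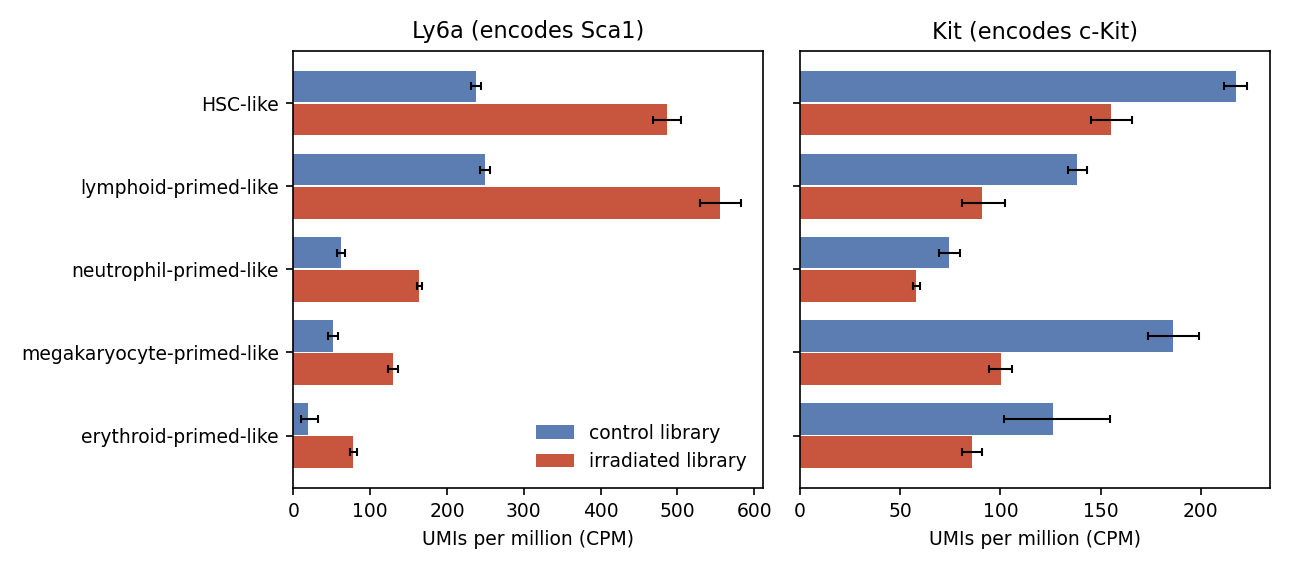
Level of Ly6a (left) and Kit (right) in CPM (UMIs per 1000000, horizontal axes) in 5 classes of the control and irradiated libraries, 1 library each; whiskers are exact 95% intervals for counting error. Ly6a in neutrophil-primed cells stood at 61.9 CPM in control and 164 CPM in irradiated cells.

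**Figure D3:**
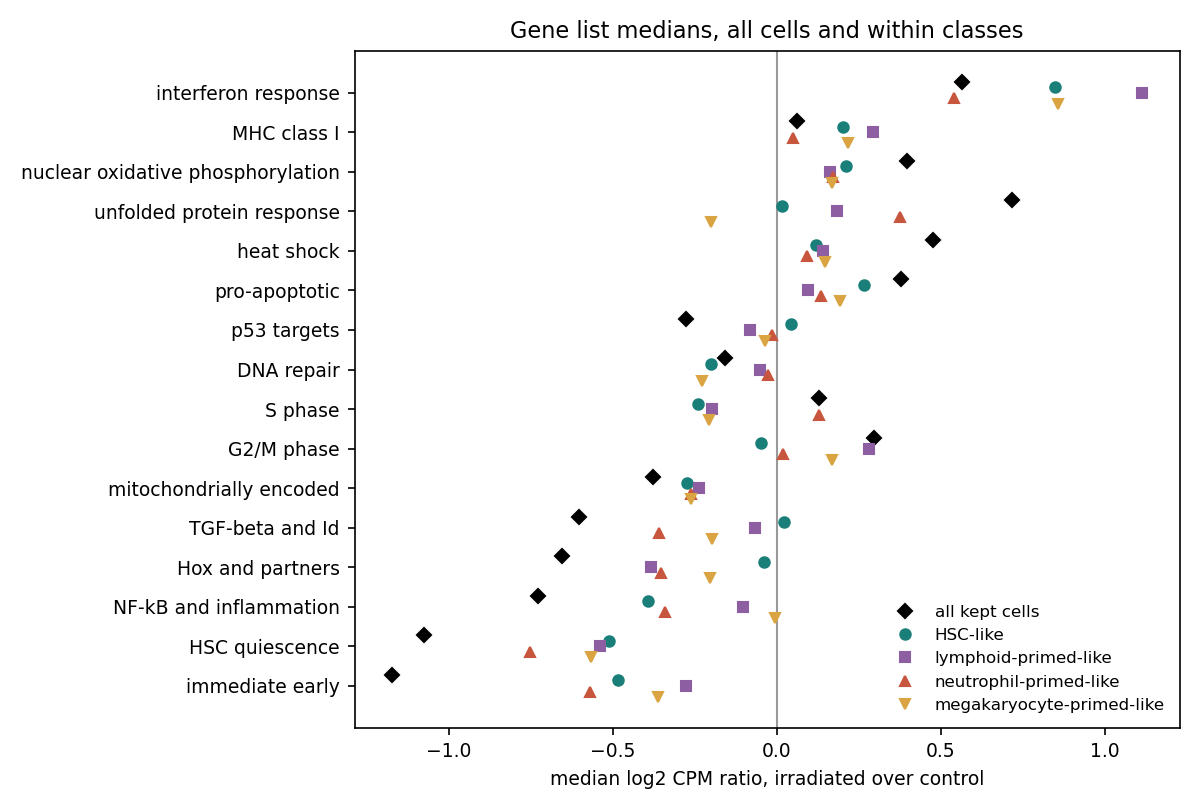
Median log2 CPM ratio of irradiated over control (horizontal axis) for 16 gene lists, over all kept cells and within the 4 compared classes; each point is 1 list in 1 set of cells, and there are no error bars because each group has 1 library. Interferon response medians lie between 0.54 and 1.11 within classes.

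The last comparison asks what share of cells carried an S or G2/M phase call. At 5000 UMIs per cell, 52.9% (51.7 to 54.0) of control cells and 79.4% (78.2 to 80.5) of irradiated cells were called in S or G2/M, and 53.9% and 80.0% without thinning. The difference lay in G2/M calls, at 21.7% and 44.9%, more than in S calls, at 31.2% and 34.5%. Within classes the S or G2/M shares were closer: 21.3% (19.4 to 23.2) and 14.0% (10.7 to 17.9) in HSC-like cells, 16.1% and 12.95% in lymphoid-primed cells, 77.6% and 80.6% in megakaryocyte-primed cells, 89.2% and 92.6% in neutrophil-primed cells and 89.5% and 90.7% in the unnamed cycling clusters. G2/M calls alone were 37.1% and 47.4% in megakaryocyte-primed cells, 51.3% and 50.7% in neutrophil-primed cells and 39.5% and 49.3% in the unnamed clusters. Phase calls alone do not show cycling, and free RNA in the droplets enters them. The difference in called cells was 26.5 points, and that in cells with at least 1 UMI of Mki67 at the same depth was 13.2 points (24.1% and 37.3%). Those Mki67 shares were 5.23% and 7.77% in HSC-like and 3.59% and 7.25% in lymphoid-primed cells, the lowest of the classes compared, and 45.3% and 45.7% in the unnamed cycling clusters, with all cells at 5000 UMIs. The unnamed clusters held 37.9% of control and 33.1% of irradiated cells, and Dntt, a lymphoid-primed marker, was among the top genes of one. Cycling stem-like and lymphoid-like cells may therefore lie in them. The low phase and Mki67 shares of the HSC-like and lymphoid-primed classes may thus be set in part by the clustering. They do not show whether cycling differed in such cells.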

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

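The tests of depth, of doublets, of the Sca1 gate, of the mix of classes, of free RNA for the granule genes, and of the gain per cell and the gain profiles of the interferon genes were chosen only after the results were seen, while the tests of the summed interferon gain in CPM and of handling were chosen before.

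Among the lists other than cell type markers, 2 had medians of opposite signs in different classes that both lay outside the central 95% of random lists. The unfolded protein response list was higher in irradiated neutrophil-primed cells (median log2 ratio 0.38, with 0.22 and 0.23 within their 2 clusters) and lower in irradiated megakaryocyte-primed cells (-0.20), a difference of 0.576 that was not tested. The cholesterol synthesis list was higher in lymphoid-primed cells (0.17) and lower in megakaryocyte-primed cells (-0.41), a difference of 0.575 that was not tested. Its lymphoid-primed value changed sign under 3 alternatives, and only 3 of 10 alternatives left it as reported. Of the cell type marker lists, on which the classes themselves rest, those of mast cells and basophils (-1.10 in megakaryocyte-primed and 0.49 in neutrophil-primed cells) and of monocyte/dendritic-primed cells (0.38 in lymphoid-primed and -0.18 in neutrophil-primed cells) did so too, also untested. Neither held under all alternatives. The value of -1.10 turned to 2.05 with all barcodes, 1.99 at a limit of 5% mitochondrial UMIs and 1.53 without each gene's 10 cells with the most UMIs. The value of -0.18 turned to 0.066 (percentile 48.5) with each cell weighted equally and 0.045 (percentile 44.2) with cells thinned.

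Neutrophil-, megakaryocyte- and erythroid-primed cells together held 8.83% of the control library and 52.4% of the irradiated library, a difference of 43.5 points. Deeper irradiated cells do not account for it, since the difference was 45.8 points (95% interval 44.2 to 47.3) with every cell thinned to 5000 UMIs. Without the 6% of cells with the highest doublet scores it was 36.3 points (34.8 to 37.8), so the highest-scoring cells do not account for it. Doublets that the scores miss are not excluded, since these scores marked few cells. The neutrophil-primed class also took 1 cluster there in place of 2, as it did with marker genes left out of clustering, where the difference was 35.9 points (34.46 to 37.35). Entry into the Sca1 gate through a higher Ly6a level stays open. Ly6a was higher in the irradiated cells of all 3 classes, with a lowest ratio of 2.52 (2.19 to 2.91), so progenitors of these classes that otherwise lie below the gate may have entered the sort. It was also 2.05-fold and 2.23-fold higher in HSC-like and lymphoid-primed cells, whose shares were smaller. A shift in what the stem and progenitor pool produces 15 days after irradiation also stays open as an untested hypothesis, as does the animals' state behind a single library per group. Sorting on a marker that irradiation does not raise, or protein levels of Sca1 per class, would separate the gate from the pool.

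Interferon response genes were higher in the irradiated cells of each of the 4 compared classes, and the mix of classes does not account for this, since the lowest of the within-class medians was 0.54 and lay at percentile 100 of the random lists, although cells that differ within a class are not excluded. The highest summed gain of the list over the lowest was 2.65 (2.49 to 2.81) in CPM, for lymphoid-primed over neutrophil-primed cells. In UMIs per cell the gains of this pair were close, at 27.2 (26.03 to 28.35) and 25.67 (24.58 to 26.72). The CPM ratio therefore does not argue against free RNA spread evenly over cells. In UMIs per cell the highest over the lowest was 1.435 (1.34 to 1.54), for lymphoid-primed over megakaryocyte-primed cells. Free RNA alone gives alike gains, but how free RNA follows depth was not measured. Free RNA of 1 source as the whole cause adds its genes in 1 proportion. Between lymphoid-primed and megakaryocyte-primed cells, each a single cluster, the distance between the gain profiles over all members was 0.363, against 0.0356 to 0.0755 in draws from 1 profile. This argues against free RNA of 1 source as the whole cause, but not as a part of it. The draws hold counting error only, and a different mix of cells within a cluster could also set the profiles apart. Handling or the state of the animals cannot be told apart from irradiation for these genes, because there was 1 library per group. An interferon response that lasts to day 15 is a hypothesis left open, and another pair of libraries would test it.

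Granule genes of neutrophil progenitors were higher in irradiated HSC-like and lymphoid-primed cells, with Ctsg at 28.8 and 100.4 CPM in HSC-like cells and 44.5 and 196 CPM in lymphoid-primed cells, where 10 irradiated cells held 34.3% and 40.9% of its UMIs and the fold ran from 1.80 to 5.93 and from 1.89 to 5.53 over the alternatives. The sizes differed by gene, and Prtn3 stood at 617.4 and 731.7 CPM in HSC-like and 472.3 and 597.5 CPM in lymphoid-primed cells. The neutrophil-primed marker list had medians of 0.77 and 0.64 in these classes. Over the alternatives the lymphoid-primed median fell to 0.14 and its percentile to 93.75. In lymphoid-primed cells free RNA does not account for the whole difference in Ctsg, since 1 source keeps its genes in 1 ratio: the gain of Ctsg over that of Elane was 4.48 times (3.26 to 6.46) the ratio of Ctsg to Elane in irradiated erythroid-primed cells (2.02), and 2.69 times (1.91 to 4.03) without the 10 cells with the most Ctsg. In HSC-like cells free RNA stays open for Ctsg, since the value was 1.42 times (1.10 to 1.85) with these cells and 1.07 times (0.816 to 1.42) without them, although Ctsg was lower in irradiated megakaryocyte-primed (147.3 and 74.2 CPM) and erythroid-primed cells (128.8 and 36.7 CPM, from 34 control cells), and neither Mpo nor Prtn3 was higher in erythroid-primed cells. The cells left out were picked by their Ctsg, so leaving them out tends to lower this ratio. The value without them therefore cannot decide. The irradiated erythroid-primed level of Ctsg was below its gain of 71.65 CPM in HSC-like cells. HSC-like cells are shallower, so equal free RNA per cell also gives a higher CPM there, and this comparison decides nothing. For Elane it stays open too: its CPM was alike in irradiated lymphoid-primed (18.3), megakaryocyte-primed (20.4) and erythroid-primed cells (18.1), with a ratio of the highest to the lowest of 1.12 (0.936 to 1.35), but it was 26.8 in HSC-like cells, and UMIs per cell were 1.79-fold higher (1.34 to 2.43) in erythroid-primed than in lymphoid-primed cells, and no value shows which scale free RNA follows. Early myeloid priming of these cells, or cells of another class placed in these clusters, stay open and untested.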

How the results depend on the processing

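The alternatives that leave out marker genes from clustering, the 6% of cells with the highest doublet scores, or each gene's 10 cells with the most UMIs were chosen only after the results were seen. With 1 library per group, none of them speaks to variation between animals, and no paired analysis was possible because each group has a single library. Of 401 alternative values for lists over all cells 388 left the list inside or outside the central 95% of random lists as reported, 6 moved it in and 6 moved it out, and 1 turned the sign of a list outside it. Lists within classes were less stable. Of their 1341 values 1163 stayed as reported, 73 moved the list in, 50 moved it out, 31 moved it out with the other sign, and 24 turned the sign of a list outside it. Interferon response medians within the 4 classes stayed above 0 at percentile 99.99 or higher under all 10 alternatives. Of 155 named genes, 62 differed at least 2-fold. Of their 558 alternative values 555 kept the sign, and 24 fell below 2-fold. Within classes 328 of 528 values for named genes lay inside the counting interval of the value reported, 2 changed sign, and Ly6a, Kit and Cdkn1a kept their sign in each class. The causes of the shifts in the values given next were not tested unless stated.

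The counts of genes moved with the thresholds by construction: 127 higher and 434 lower at a mean CPM of at least 5, 26 and 61 at 50, 300 and 432 at a ratio of 1.5, and 20 and 26 at a ratio of 3. The other 9 alternatives gave 53 to 62 higher and 101 to 132 lower. Iglc1 turned to 0.59 with each cell weighted equally and to 0.62 with cells thinned, and Ebf1 to 1.41 without the clusters of mature cells, which hold the B lineage cells. The megakaryocyte-primed markers had a median of 0.40 at percentile 96.1 at a mean CPM of at least 20, and the sort and stem surface genes 0.30 with no minimum.

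The share differences kept their direction for the 5 largest named classes, with these sizes in points. For HSC-like cells the difference was -16.8 at resolution 0.5, -14.8 with each cell named by its markers, -11.6 at 5% mitochondrial UMIs, -16.6 with cells marked by Scrublet kept, -21.1 with 30 neighbours from all cells, -16.4 with cycle genes allowed and -16.5 with marker genes left out. For lymphoid-primed cells it was -26.9 at resolution 0.5, -26.0 at resolution 2, -19.3 with all barcodes, -31.2 at 5% mitochondrial UMIs, -26.8 with marked cells kept, -42.3 with 30 neighbours, -30.7 thinned, -24.9 with cycle genes, -26.3 without marker genes and -26.1 without the 6%. For neutrophil-primed cells it was 20.4 at resolution 0.5, 24.7 by each cell's markers, 18.7 with all barcodes, 25.8 at 5% mitochondrial UMIs, 20.2 with marked cells kept, 34.1 with 30 neighbours, 30.4 thinned, 21.4 with cycle genes, 20.3 without marker genes and 20.04 without the 6%. For megakaryocyte-primed cells it was 3.49 by each cell's markers, 6.33 at 5% mitochondrial UMIs and 8.61 with 30 neighbours, and at resolution 0.5 these cells joined the erythroid-primed cluster, whose difference was then 16.1. The erythroid-primed difference was 7.10 thinned, and that of T/NK lineage cells turned to -0.102 by each cell's markers.

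Within HSC-like cells the endothelial and stromal markers turned to 1.93 with 30 neighbours, S phase genes to 0.15 with all barcodes and MHC class II genes to 0.66 at 5% mitochondrial UMIs. Within lymphoid-primed cells S phase genes turned to 0.084 at 5% mitochondrial UMIs, 0.12 with marked cells kept and 0.18 at resolution 2, G2/M genes to -0.078 (percentile 97.4) without the top 10 cells, and cholesterol synthesis genes to -0.050 at 5% mitochondrial UMIs, -0.038 with 30 neighbours and -0.33 (percentile 82.1) without the top 10 cells. The top 10 cells are a larger part of the 193 irradiated than of the 1787 control lymphoid-primed cells. Leaving them out can therefore lower ratios in general, and both lists still lay in the upper part of the random lists. Within megakaryocyte-primed cells the mast cell and basophil markers turned from -1.10 to 2.05 with all barcodes, 1.99 at 5% mitochondrial UMIs and 1.53 without the top 10 cells, where a few control cells carried them, Mcpt8 to 1.00 with all barcodes and 0.86 at 5% mitochondrial UMIs, and G2/M genes to -0.027 with all barcodes. Within neutrophil-primed cells the HSC markers turned to 0.38 and the Hox list to 0.00995 with 30 neighbours, monocyte/dendritic-primed markers to 0.066 with each cell weighted equally and 0.045 thinned, and erythroid-primed markers to -0.36 both with all barcodes and with marked cells kept. NF-kB genes there turned to 0.066 at 5% mitochondrial UMIs and 0.019 at resolution 2, and immediate early genes to 0.017 with all barcodes and 0.054 with 30 neighbours, with -0.013 at percentile 26.7 with marked cells kept.

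The difference in S or G2/M calls was 6.98 points with at least 5 UMIs over the G2/M list, a measure that over 90% of cells in each library passed and that says nothing on stability. It was 20.6 at 5% mitochondrial UMIs and 21.1 at 10000 UMIs, and the other 5 alternatives gave 25.5 to 27.2.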

Other observations

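Genes of protein folding and energy metabolism were higher over all irradiated cells. Of 16 unfolded protein response genes 13 were higher (median log2 ratio 0.72, percentile 100), with Hspa5, the main chaperone of the endoplasmic reticulum, at 264 and 611 CPM and Calr, a calcium-binding chaperone, at 711 and 1180.1 CPM. Within neutrophil-primed cells 11 of the 16 were higher (median 0.38, percentile 100), in part by the mix of their 2 clusters, within which the medians were 0.22 and 0.23. Heat shock genes had a median of 0.48 (percentile 99.6), with the mitochondrial chaperone Hspd1 at 353 and 602 CPM. Glycolysis genes had a median of 0.36 (percentile 99.3), with Pgam1 1.77-fold and Gapdh 1.44-fold higher. Both lists had smaller medians within HSC-like, lymphoid-primed, megakaryocyte-primed and neutrophil-primed cells. In that order they were 0.12, 0.14, 0.15 and 0.09 for heat shock and 0.10, 0.10, 0.01 and 0.29 for glycolysis. The differences over all cells may therefore rest in part on the mix of classes, which was not tested for these lists. Of 77 nuclear oxidative phosphorylation genes 52 were higher and 2 lower (median 0.40, percentile 100), with Atp5k and Uqcrq highest, and within the 4 compared classes the medians lay between 0.16 and 0.21. The mitochondrially encoded subunits of the same complexes went the other way, with 8 of 13 lower (median -0.38, percentile 0), mt-Co3 and mt-Atp6 among them, and mt-Nd4l and mt-Atp8 slightly higher.

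Among antigen presentation genes, class II members differed in opposite directions over all cells. H2-Eb1 and H2-Aa, which encode the peptide-binding chains, were 3.37-fold and 2.22-fold higher in the irradiated library, while H2-Ob and H2-DMb1, which act in peptide loading, stood at 34.8 and 10.9 CPM and at 39.2 and 26.1 CPM. H2-Eb1 and H2-Aa were among the top genes of the dendritic cluster, which held 0.389% of control and 1.56% of irradiated cells, and within the 4 compared classes the list's medians lay between -0.36 and -0.05. Under alternatives they reached 0.66 in HSC-like, 0.71 in megakaryocyte-primed and 0.26 in neutrophil-primed cells, so no direction within classes is drawn. Over all cells the list had a median of 0.29 (percentile 96.5), and it ranged from -0.18 to 0.87 over the alternatives. Chromatin regulators had a median of -0.22 (percentile 3.58), with Tet1 and Kdm6b both 2.41-fold lower and Idh2 and Ezh2 slightly higher. Antioxidant genes had a median of 0.24 (percentile 86.3), with Gsr, the glutathione reductase, 2.20-fold higher and Cat, the catalase, 1.30-fold lower. Of 80 ribosomal protein genes 75 were neither higher nor lower (median -0.04, percentile 0), and the largest ratio was that of Rps27l, a p53-inducible relative of a ribosomal protein, at 519 and 812 CPM. Cholesterol synthesis genes had a median of -0.08 (percentile 65.2), adhesion and homing genes -0.04 (percentile 44.2) with Cd44 and Cxcr4 lower, and the 4 measured sex-linked genes -0.45 (percentile 6.52).

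Cdkn1a was lower over all irradiated cells and higher in the irradiated cells of each compared class. In control cells it stood highest in the lymphoid-primed class (155 CPM) and lowest among the compared classes in the neutrophil-primed class (42.6 CPM), the classes with the smaller and the larger share of the irradiated library. Erythroid-primed markers were higher within megakaryocyte-primed cells (median 0.74, percentile 100, 6 of 9 members higher). This was not particular to that class. Their median was 0.58 in lymphoid-primed cells, at percentiles from 99.09 to 99.93 over the alternatives. It was 0.36 in neutrophil-primed cells, where it changed sign under some alternatives, and 0.01 in HSC-like cells. Free RNA was not tested for this list. Lymphoid-primed markers were lower within HSC-like cells (-0.67, percentile 0) and within megakaryocyte-primed cells (-1.82, percentile 0).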
